A study of Drosophila melanogaster with 3 samples.

How the data were processed

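The data were chromatin immunoprecipitation and sequencing (ChIP-seq) peak lists from Drosophila melanogaster embryos of mixed sex, 0 to 24 hours old. Per the labels, the embryos came from a transgenic line in which the protein encoded by CG10565 carried a C-terminal eGFP tag, and chromatin sheared to fragments of 200 to 800 bp was precipitated with an antibody against GFP. The samples were 3 biological replicates, which the labels number 1, 2 and 4, and they formed 1 group. The labels give no second condition, so the comparisons set regions against regions within this group.

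Per the deposited description of the lists, the authors called peaks in each replicate from its own alignment and in the pool of the 3 alignments, with 1 control alignment behind each list. Per the same description, they then derived an optimal list from the replicate and pooled lists by the irreproducible discovery rate (IDR). This rate measures how alike regions rank across replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each region carries a signal value made by the authors' peak caller, and this deposited signal served only to rank and filter regions within a list. Read counts were not analysed here, so the depth of each replicate is unknown and no interval below covers the depth of sequencing. The control itself was not analysed here.

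The authors gave lists for the assemblies dm6 and dm3. In dm6 the pooled list and each replicate list held 30000 regions and the IDR list held 1143. The most frequent width was 370 bp in the pooled list and in replicate 1, 350 bp in replicate 2 and 600 bp in replicate 4. All 1143 IDR peaks had the coordinates of a pooled call. No pooled call clear of the IDR peaks reached the signal of 106 of the weakest IDR peak, so the IDR list corresponds to the strongest 1143 pooled calls. Some IDR peaks overlap each other, and the 1143 peaks form 1131 separate regions. The dm6 lists were annotated with Ensembl release 115 for release 6 of the assembly, with 18277 genes and 23697 distinct transcription start sites (TSSs) after 5896 transposable elements had been left out. The ends of the calls lay within the chromosome lengths of the reference sequence. The dm3 lists were used for counts, the X share and the comparison of replicates. Coordinates below are 1-based dm6 positions.

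The background for each region test was the 28738 pooled calls that overlapped no IDR peak by 1 bp or more. These are weaker calls of the same pool, so a difference from them is also a difference between strong and weak calls. A summit counted as promoter within 500 bp of an annotated TSS, and otherwise as UTR exon, coding exon, other exon, intron or intergenic in this order. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within the 6 classes, the 24 gene lists and the 16 motifs. Intervals of shares are 95% Wilson intervals and those of odds ratios are 95% exact intervals; they cover counting error only and treat regions as independent. Genes with an IDR summit within 500 bp of a TSS were compared with the rest of the 7478 genes that had any tested pooled call there. Motifs were searched on both strands within 100 bp of the summit, and each IDR peak was matched to 1 other pooled call of the same promoter status and the same of 10 bins of GC content over 201 bp. Replicate support counted IDR summits inside the top 1143 calls of a replicate, against 100 random draws of as many calls. Agreement in rank was measured with Spearman's rho across IDR peaks, which are not independent replicates, and has no p-value.

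The gene lists, motifs, tests, named items and most alternatives were fixed before the data were examined. The named items were the 20 IDR peaks with the highest signal, up to 4 bound members of each list past an adjusted p of 0.05, up to 2 bound members of each other list, and CG10565. Gene lists were built from symbols and cover the ribosome, translation, protein quality control, mitochondria, splicing, the cell cycle, small RNA genes, Polycomb targets and genes of particular cell types or stages. The alternatives were the 571 IDR peaks with the highest signal, a background of the 13763 stronger of the other pooled calls, random positions, each replicate left out, TSS windows of 250 and 1000 bp, other gene backgrounds, another motif window and matching, other definitions of support, and the dm3 lists. The shares by rank, the tests outside promoters and with no promoter class, the nearest-TSS assignment, tRNA loci, the X test within each replicate list, the counts with overlapping IDR peaks taken once, 20 further matched draws and the open sequence scan were added after the data had been seen.

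The tests were checked on simulated data in sets of 50. With 1143 calls drawn at random from the pooled list, the TSS test made a call in 0% of the sets, the X test in 2%, and 0.04 of the 24 gene lists passed on average. When calls at cytosolic ribosomal protein genes were drawn 5 times as often as others, the list was called in 100% of the sets, and in 32% when drawn 2 times as often. For the proteasome list the figures were 38% and 2%, so short lists had little power. The DNA replication-related element and the Zelda site, which are rare in the background, were each called in 100% of the sets when planted in 5% of the windows. Power for smaller excesses and for frequent motifs such as the TATA box was not tested. CACTGT planted in either direction read outward in 49.7% of the hits on average, and planted outward in 100.0%. The natural hits in these windows were erased before planting, so these values check only how direction was counted. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the plots.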

Results

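The binding of the CG10565 protein was profiled by anti-GFP ChIP-seq in whole embryos that carried an eGFP-tagged copy, in 3 biological replicates. CG10565 encodes a J-domain protein related to human DNAJC2, a chaperone associated with ribosomes that has also been studied on chromatin. The values below describe 1143 IDR peaks, the regions of the authors' optimal list, and 28738 weaker calls from the pool of the same replicates. The IDR peaks correspond to a cut on pooled signal, and 1008 of them had the summit inside a call of all 3 replicates. Signal is the authors' value for a peak and has meaning only within its list. The lists carry no read counts, so the depth behind each peak is unknown.

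The strongest peaks lay at promoters and in introns of genes with varied functions. The peak with the highest pooled signal, 1018, had its summit at X 2703879, 27 bp upstream of the TSS of Ugalt (FBgn0024994), which encodes a transporter of UDP-galactose. It was followed by the promoter of CG14100 (3L 19590622, signal 976), a promoter of the wing vein gene px (2R 22514306, signal 929) and an intron of ush (2L 481105, signal 835), which encodes a cofactor of GATA transcription factors. A single peak at 3L 22878755 to 22879054 (signal 813) had its summit 97 bp downstream of the TSS of Chro, a chromatin protein, and 202 bp upstream of that of Ssl1, a subunit of the general transcription factor TFIIH. A promoter of ph-p, a Polycomb group gene, held a peak with a signal of 794 whose summit lay 479 bp upstream of the TSS.

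Of the 20 peaks with the highest signal, 15 were at a promoter and 5 in an intron. The intronic peaks were those in ush, CG11050, the protein kinase gene Lk6, the junction gene cno and CG32772. Mitochondrial ribosomal protein genes lay beside 3 of these peaks. The peak at 3R 15229389 to 15229669 (signal 649) lay between Art3 and mRpS10, the peak at 2L 13835341 to 13835584 (signal 551) between CenG1A and mRpS23, and the peak at 2R 15217616 to 15217875 (signal 547) upstream of mRpL41 and within 500 bp of the start of lncRNA:CR44463. PNPase, a mitochondrial RNA-processing enzyme, had a summit 69 bp downstream of a TSS with a signal of 632. The remaining promoters were those of CG13921 (signal 582), lncRNA:CR31840 (568), CG31145 (558), the divergent pair CG9147 and Fbw5 (553), CG1888 (549) and CG18549 (518). In 18 of the 20 peaks the summit fell inside a top 1143 call of every replicate. The exceptions, CG31145 and the CG9147 and Fbw5 pair, were supported by 2 replicates under this rule. Calls that overlapped the CG31145 peak still ranked 27, 32 and 10 in replicates 1, 2 and 4. The peak of the CG9147 and Fbw5 pair had no overlapping call in replicate 2.

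Across the genome, promoters were the main location of the IDR peaks. Summits of 628 of the 1143 IDR peaks (54.9%, 95% interval 52 to 57.8) lay within 500 bp of a TSS, against 6490 of 28738 other pooled calls (22.6%, interval 22.1 to 23.1). The odds ratio was 4.18 (interval 3.70 to 4.72) and Fisher's exact test gave p = 5.14e-118. Of the length of the main chromosomes, 13.3% lies within 500 bp of a TSS. Against random positions of the same chromosome arms, of which 13.6% were at a TSS, the odds ratio was 7.77.

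Away from start sites, few IDR summits lay in exons. Coding exons held 4 IDR summits (0.350%) against 9.51% of the other calls, with an odds ratio of 0.0334 and adjusted exact p = 1.14e-41. UTR exons held 13 (1.14%) against 7.1%, with an odds ratio of 0.150 and adjusted exact p = 1.20e-20. Summits within 500 bp of a TSS are not in these counts. With no promoter class, coding exons still held 4 IDR summits, but UTR exons held 95 (8.31%) against 11.8% (odds ratio 0.676, adjusted exact p = 0.000405). In that setting the intergenic difference turned round, to 41.0% of IDR summits against 29.2% (odds ratio 1.69, adjusted exact p = 2.36e-16), and introns did not differ past the threshold (odds ratio 1.10, adjusted exact p = 0.138). Introns held 359 IDR summits (31.4%) against 39.6% of the other calls (odds ratio 0.698, adjusted exact p = 2.16e-08), and intergenic sequence held 132 (11.5%) against 20.3% (odds ratio 0.514, adjusted p = 2.66e-14). Exons of other kinds did not differ past the threshold (7 summits, odds ratio 0.662, adjusted exact p = 0.341). These shares add up to a whole, so a higher promoter share lowers the others. Among the 515 IDR summits outside promoters, introns held 69.7% against 51.2% of the other calls (odds ratio 2.20, adjusted exact p = 8.80e-17), and the intergenic shares were 25.6% and 26.2% (adjusted p = 0.800).

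**Figure D1:**
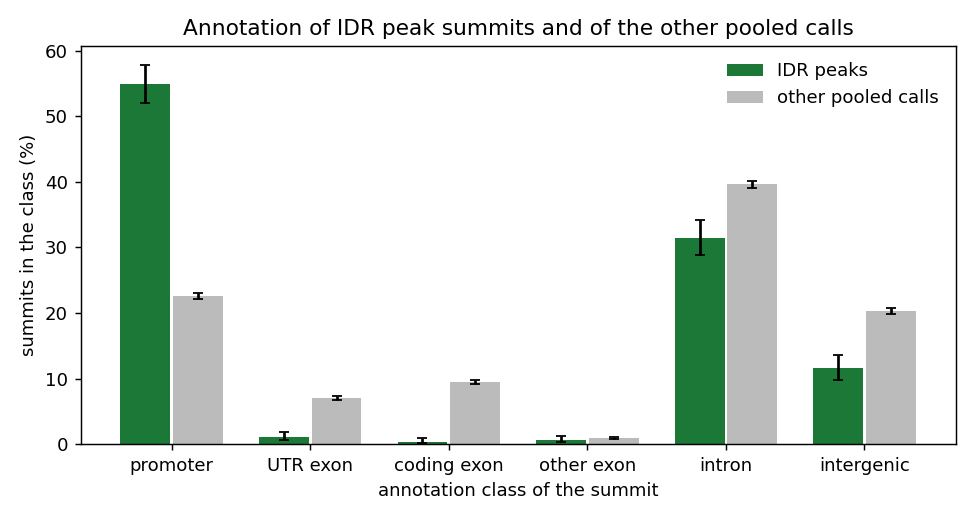
Bars give the percentage of summits in each annotation class (horizontal axis) for IDR peaks and for the other pooled calls, with 95% Wilson intervals. Promoter summits make up 54.9% of the IDR peaks and 22.6% of the other calls, and coding exons 0.350% and 9.51%.

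The share at promoters was higher in strong than in weak calls of the pooled list and of each replicate. Among pooled calls of ranks 1 to 250, 64.4% (interval 58.3 to 70.1) were at a TSS, and among those of ranks 20001 to 30000, 16% (interval 15.3 to 16.8). The pooled share was 50.1% in ranks 501 to 1143 and 49.7% in ranks 1144 to 2500, so it did not drop at the edge of the IDR list. In ranks 1 to 250 of the replicates the shares were 64.0% in replicate 1, 60% in replicate 2 and 62.4% in replicate 4, with overlapping intervals. In ranks 1144 to 2500 they were 52.3% (49.7 to 55.0) in replicate 1, 31.1% (28.7 to 33.6) in replicate 2 and 44.6% (42.0 to 47.2) in replicate 4.

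**Figure D2:**
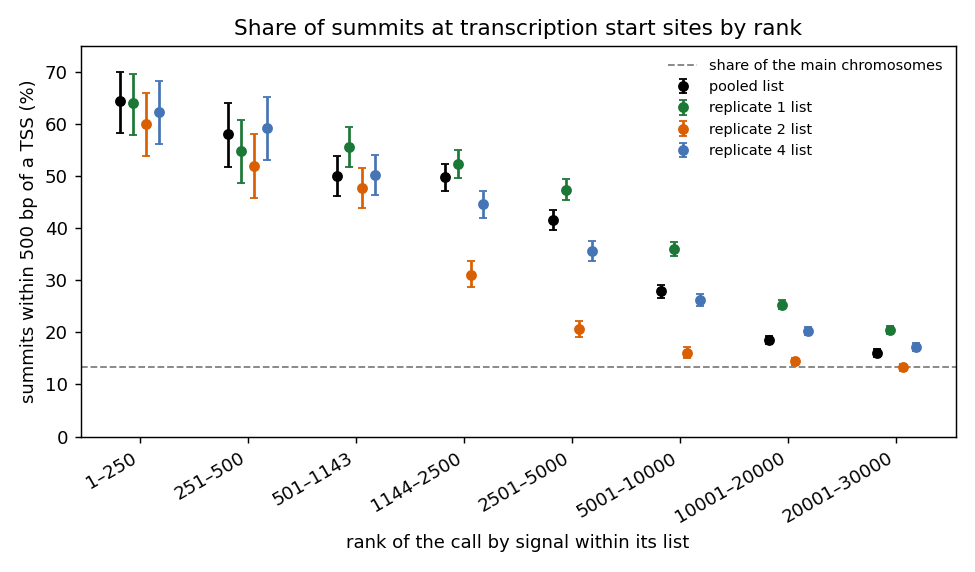
Points give the percentage of summits within 500 bp of a TSS (vertical axis) by rank of the call within the pooled list and each replicate list (horizontal axis), with 95% Wilson intervals. The dashed line is the 13.3% of the main chromosomes within 500 bp of a TSS. Replicate 2 falls to 31.1% in ranks 1144 to 2500, below replicates 1 and 4.

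The X chromosome held a larger share of the IDR peaks than of the weaker calls, though not in every replicate list. Of the IDR peaks on the major arms, 205 of 1137 (18.0%, interval 15.9 to 20.4) were on the X, against 4019 of 28182 other pooled calls (14.3%, interval 13.9 to 14.7). The odds ratio was 1.32 (interval 1.13 to 1.55, Fisher's exact test, p = 0.000560). The X makes up 17.8% of the length of these arms, so the IDR share is close to the length and the weaker calls fall below it. With the top 1143 calls of a replicate set against its other calls, the odds ratio was 0.966 in replicate 1 (exact p = 0.710), 1.75 in replicate 2 (exact p = 2.19e-12) and 1.22 in replicate 4 (exact p = 0.0118). The Ugalt, ph-p and CG32772 peaks named above are on this chromosome. The other arms held 226 (2L), 198 (2R), 251 (3L) and 257 (3R) IDR peaks, chromosome 4 held 6 and the Y held 0. The embryos were of mixed sex, and how the copy number of the X entered the signal through the control was not examined.

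Genes of the cytosolic ribosome carried IDR peaks more often than other genes. Of 80 cytosolic ribosomal protein genes with a tested call, 32 (40%, interval 30 to 51.0) had an IDR summit within 500 bp of a TSS, against 866 of 7398 other genes (11.7%). The odds ratio was 5.03 (interval 3.09 to 8.08), and Fisher's exact test gave an adjusted p of 3.60e-09 over the 24 lists. The 32 genes corresponded to 32 distinct peaks. Those with the highest signal were at RpS27 (FBgn0039300, 3R 25247536, signal 283, 22 bp upstream of the TSS), RpL7 (FBgn0005593, 2L 10201014, signal 278, 10 bp downstream), RpL32 (FBgn0002626, 3R 30046313, signal 268, 152 bp upstream) and RpLP0 (FBgn0000100, 3L 22076078, signal 256, 14 bp upstream of a TSS). Each of these 4 peaks was in the top 1143 calls of all 3 replicates. The odds ratio fell to 2.76 (14 of 80 genes, adjusted exact p = 0.0198) when replicate 2 was left out, and was 10.5 with all annotated genes as the background.

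Genes for transfer RNA had fewer IDR peaks. An IDR summit was found at 5 of 132 tested tRNA genes (3.79%, interval 1.63 to 8.56), with an odds ratio of 0.284 (interval 0.0906 to 0.684) and an adjusted p of 0.0199 by Fisher's exact test. These 5 genes shared 4 peaks. The strongest, with a signal of 298, lay 181 bp upstream of tRNA:Tyr-GTA-1-8 and was supported by 3 replicates. The peak near tRNA:Trp-CCA-2-2 and tRNA:Gly-GCC-1-9 (signal 118) and the peak at tRNA:His-GTG-1-3 (signal 117) were each supported by 1 replicate. With clustered tRNA genes counted as loci, 4 of 82 were bound (odds ratio 0.371, adjusted exact p = 0.325). The call was also lost with a TSS window of 250 bp (0.373, adjusted exact p = 0.516) and without replicate 1 (0.118, adjusted exact p = 0.0567), and the odds ratio was 0.0959 to 0.118 with any 1 replicate left out. Many tRNA genes have near-identical copies, and how the authors placed reads that match several copies is not given in the sources used here.

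No other list passed the adjusted threshold. Mitochondrial ribosomal protein genes were bound in 10 of 46 cases (21.7%, odds ratio 2.05, adjusted exact p = 0.379), and mRpS10 and mRpS23 were their strongest members. Bound fractions in the other translation lists were 5 of 26 initiation and elongation factors (odds ratio 1.75), with peaks at eIF6 and eIF4EHP, 4 of 18 aminoacyl-tRNA synthetases (2.10), including SerRS and GluProRS, and 3 of 21 ribosome biogenesis and RNA polymerase I genes (1.22), including Ns2. Cell cycle and DNA replication genes were bound in 5 of 23 cases (2.04), with peaks at Cdk1 and RnrS, heat shock proteins and chaperones in 3 of 16 (1.69), including Hsp27 and Hsp83, and respiratory chain and ATP synthase genes in 6 of 46 (1.10), including ND-ASHI and ND-MWFE. The cell cycle count was 0 of 23 without replicate 1, 1 of 23 (0.580) without replicate 2 and 3 of 23 (2.04) without replicate 4. Splicing factors were bound in 2 of 21 cases (0.771; U2af50 and snRNP-U1-C), Polycomb targets in 2 of 19 (0.862; ph-p and NK7.1), snoRNA and scaRNA genes in 4 of 72 (0.428), including snoRNA:Or-CD11a and snoRNA:Or-aca5, and the proteasome in 1 of 19 (0.406; Rpn5). The snoRNA and scaRNA result depended on the setting. It was 21 of 137 (1.47) with a TSS window of 1000 bp, 4 of 72 (0.925) without replicate 1 and 0 of 33 by the nearest TSS alone.

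The remaining lists had few tested members. Bound were elav among 7 neuronal genes, Msp300 and sls among 11 muscle genes, Obp99b among 9 odorant-binding protein genes and Cyp6u1 among 30 cytochrome P450 genes. None was bound among 34 chemoreceptor genes (interval 0 to 10.2%, unadjusted exact p = 0.0290, adjusted p = 0.232), 21 cuticle protein genes, 15 snRNA genes, 11 germline genes, 7 segmentation and dorsoventral patterning genes, 5 hemocyte genes and 3 histone genes, the members of each list that had any tested call. These counts cover summits within 500 bp of a TSS only. The hemocyte list includes ush, which held 5 IDR peaks inside the gene but outside this window. With all annotated genes as the background, 7 lists passed, of which the added ones were mitochondrial ribosomal proteins (higher) and histone, snoRNA and scaRNA, cuticle protein and chemoreceptor genes (lower).

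**Figure D3:**
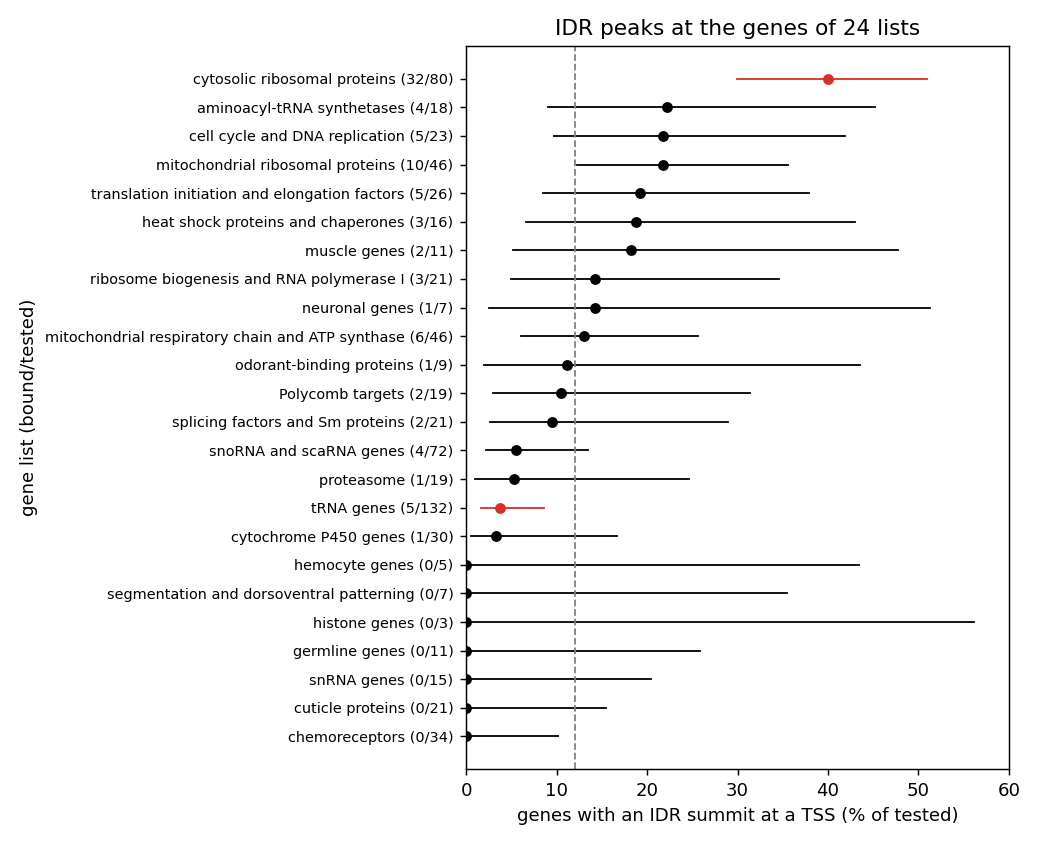
Points give the percentage of tested genes with an IDR summit within 500 bp of a TSS (horizontal axis) for the 24 lists (vertical axis, bound and tested genes in brackets), with 95% Wilson intervals. Red marks lists past an adjusted exact p of 0.05, and the dashed line is the 12.0% of all tested genes; cytosolic ribosomal proteins lie at 40% and tRNA genes at 3.79%.

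Known promoter and factor motifs within 100 bp of the summit did not separate the IDR peaks from matched calls in the draw used here. IDR summits at promoters lay at a median of -138.5 bp from the nearest TSS, so for most of them the TSS was outside this window. The other pooled calls at promoters lay at a median of -77 bp, and position against the TSS was not matched. Elements at the start site, such as the TATA box and the initiators, were therefore not well tested. By Fisher's exact test 0 of the 16 consensus motifs passed the adjusted threshold, and 1 had an unadjusted p under 0.05. That motif was the CA repeat, in 0.875% of IDR peaks and 2.01% of matched calls (p = 0.0338, adjusted exact p = 0.250). Its odds ratio was 0.430, lower than in any of 20 other matched draws (0.496 to 1), in none of which it passed. The DNA replication-related element occurred in 2.36% of IDR peaks and 2.89% of matched calls, the BEAF-32 core in 25.8% and 25.9%, and Motif 1 in 0.875% and 1.31%. The TATA box occurred in 36.6% and 40.5%, and the TCT initiator, a start-site element of ribosomal protein genes, in 23.2% and 20.1% (odds ratio 1.20, adjusted exact p = 0.250). The TCT initiator passed in 5 of 20 other matched draws (odds ratios 1.15 to 1.47, median 1.30) and against the stronger background calls (1.40, adjusted exact p = 0.0248), so a small excess of it is not ruled out. Shares of the Pho core were 4.46% and 2.89%, of Ohler motif 7 8.40% and 6.47%, of Ohler motif 6 1.57% and 1.05%, of the Zelda site 1.05% and 0.525%, of the E-box 6.74% and 7.35%, of the initiator 17.1% and 17.8% and of A tracts 5.16% and 5.51%. The B box of RNA polymerase III genes and the heat shock element occurred in 2 IDR peaks each. The GAGA element occurred in 3.32% and 2.10% (odds ratio 1.60, adjusted exact p = 0.250). It passed in the 571 IDR peaks with the highest signal (4.73% against 0.525%, adjusted exact p = 0.000105) and when replicate 1 or replicate 2 was left out (odds ratios 5.40 and 3.20). Each of these settings rests on a single matched draw, with GAGA in 0.525%, 0.888% and 1.62% of the matched calls, below the 2.10% of the main draw. The GAGA element did not pass when replicate 4 was left out (odds ratio 2.13, adjusted exact p = 0.351) or within 50 bp of the summit (odds ratio 0.398, adjusted exact p = 0.713). Other matched draws were made for the main setting only, where it passed in 1 of 20 (median odds ratio 1.71).

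The replicates shared many of their strongest calls. Among the top 1143 calls of each replicate, replicate 1 held 858 IDR summits (75.1%, interval 72.5 to 77.5), replicate 2 held 814 (71.2%, 68.5 to 73.8) and replicate 4 held 769 (67.3%, 64.5 to 69.9). All 3 replicates supported 439 peaks (38.4%, interval 35.6 to 41.3), where random draws gave 0.11 on average and 1 at most. Another 438 peaks were supported by 2 replicates, 248 by 1 and 18 by none. The IDR list was built from these replicate lists, so this support is not independent of it. Support by all replicates was 63.0% among the top 2286 calls and 68.7% for the 571 IDR peaks with the highest signal.

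Ranks of the shared peaks agreed in part. Spearman's rho across IDR peaks was 0.51 between replicates 1 and 4 (1123 peaks with a call in both), 0.34 between replicates 1 and 2 (1040 peaks) and 0.28 between replicates 2 and 4 (1026 peaks). Single peaks show the spread. The Ugalt peak ranked 2, 1 and 8 in replicates 1, 2 and 4, whereas the eIF6 peak ranked 286, 51 and 8186 and the elav peak 159, 2336 and 206.

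The tagged gene itself carried no IDR peak. CG10565 (FBgn0037051, 3L 21133250 to 21136353, minus strand) had 4 pooled calls in the gene or within 500 bp of it. The strongest of them had a signal of 40.1 and rank 7469, below the 106 of the weakest IDR peak. The best calls in replicates 1, 2 and 4 ranked 3932, 1321 and 789.

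The dm3 lists of the same samples gave a similar spread over the chromosomes. The dm3 IDR list held 1325 peaks, of which 265 were on 2L, 227 on 2R, 290 on 3L, 298 on 3R and 235 on the X. Chromosome 4 held 7 dm3 peaks, the mitochondrial genome 1 and unplaced sequence 2. The X share among dm3 peaks gave an odds ratio of 1.30 (Fisher's exact test, p = 0.000561), and 37.3% of the dm3 peaks were supported by all 3 replicates.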

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

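The nearest-TSS assignment, the tRNA loci, the shares outside promoters or with no promoter class, the X test within each replicate list, the counts with overlapping peaks taken once and the further matched draws were chosen after seeing the data. The TSS odds ratio stayed above 1 and past the threshold under all 9 alternatives (2.97 to 7.77), as did that of cytosolic ribosomal protein genes under all 10 (2.76 to 10.5). The X odds ratio did so under 9 of 10 (1.22 to 1.75), and fell to 0.966 for the top 1143 calls of replicate 1 against the rest of that list, so the X difference does not hold in each replicate. All 5 annotation classes past the threshold passed in all 7 alternatives fixed in advance. Of the shares computed among summits outside promoters, that of introns turned to an odds ratio of 2.20 and that of intergenic sequence lost its call (0.972), because the promoter share no longer enters the denominator. With no promoter class introns were at 1.10, short of the threshold, and intergenic sequence at 1.69, past it in the other direction, since promoter summits then count in these classes. The number of gene lists past the threshold was 7 with all annotated genes, 1 with protein-coding genes alone, which leaves no tRNA gene to test, 1 with a window of 250 bp, and 1 to 2 with a replicate left out. The tRNA odds ratio was 0.373 with the 250 bp window and 0.371 by loci, both short of the threshold with fewer units tested, and 0.0959 to 0.118 with a replicate left out. The motif count of 0 became 1 in the 571 peaks with the highest signal (GAGA), 1 against the 13763 stronger background calls (TCT initiator, odds ratio 1.40), 0 to 1 with a replicate left out, and at most 3 over 20 other matched draws, where the TCT initiator passed in 5; the cause was not tested. Support by all replicates was 63.0% with 2N calls, 68.7% in the 571 with the highest signal and, counting both remaining replicates, 46.9% to 53.8% with 1 left out. Correlations of ranks moved by less than the spread between the replicate pairs. Among lists and motifs not called in the main setting, 5 list results (all with all annotated genes) and 4 motif results moved past the threshold, and 213 and 137 did not. Of the named peaks' replicate counts, 5 of 55 changed by over 1.5 times with 2N calls. Leaving out a replicate also changes the peak set, to 563 to 678 pooled calls shared by the other replicates. It does not remove the reads of that replicate from the pool in which these calls and their background were made. Read depth is unknown, so its share in the ranks was not separated.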

Other observations

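The tests in this part were chosen after the results they bear on had been seen, except the 2 tests on the reading direction of CACTGT in weaker pooled calls, whose outcomes were stated first.

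IDR summits at promoters sat mostly upstream of the start site. Of 628 promoter summits, 86.9% (interval 84.1 to 89.4) were upstream of the nearest TSS, at a median of -138.5 bp, against 62.7% (61.5 to 63.9) and -77 bp for the other pooled calls (odds ratio 3.96, Fisher's exact test, p = 1.05e-38). Divergent pairs of protein-coding genes, such as Art3 and mRpS10, lay at 223 of 596 protein-coding promoter summits (37.4%), against 20.1% in the other pooled calls (odds ratio 2.38, exact p = 5.00e-20). In pooled calls of ranks 1144 to 2500 the share was 42.1%, and the IDR peaks did not differ from them past the threshold (odds ratio 0.823, interval 0.650 to 1.04, exact p = 0.102).

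Some long genes held several separate IDR regions each, with overlapping peaks counted as 1 region, and are named here by their counts after these were seen. CG1677 (X 7281089 to 7405797) held 9, or 7.22 per 100 kb, against 0.822 per 100 kb over the main chromosomes. Each of CHES-1-like, Tlk, the ecdysone-induced receptor gene Eip75B and ush held 5, and Hr4, Raf, rdx and tara held 4. CHES-1-like, at 27048 bp the shortest of the 9 genes, had 18.5 regions per 100 kb.

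The sequence under the IDR summits was AT-rich and was flanked by a directional element. GC content was 31.9% within 40 bp of the summit and 44.2% at 200 to 300 bp, against 39.0% and 42.1% in the other pooled calls. Over the wider window used for GC matching, pooled calls of ranks 1144 to 2500 held 34.7% GC. Ranks 1 to 250, 251 to 500 and 501 to 1143 held 35.4%, 35.2% and 34.4%. Ranks 2501 to 5000 held 35.6% and ranks 20001 to 30000 held 41.0%. AT-rich sequence in that window was therefore not particular to the IDR peaks. An open scan of 6097 8-mers within 100 bp of all IDR summits ranked CACAGTGG first. It occurred in 5.77% of IDR peaks and 1.29% of the other calls (odds ratio 4.69, adjusted exact p = 7.33e-18). In this scan 543 of the 8-mers passed an adjusted exact p of 0.05 without matching for GC content. Promoter and distal peaks were also scanned apart, and their rankings are not given here. The positions of 11 sequences were then looked at, and CACTGT, which 4 of the 10 leading 8-mers hold in either direction, was followed. Others of the 10, such as CAGGGGCG (odds ratio 6.92, the largest) and ATTTAAAA (1.97), do not hold it and were not followed further. Between 40 and 160 bp from IDR summits it read outward, forward on the right or reversed on the left, in 286 hits and inward in 84 (77.3% outward, interval 72.8 to 81.3), and 215 peaks (18.8%) had an outward hit. The outward share was 75.9% at promoters and 78.9% elsewhere, and 71.3%, 74.7% and 78.7% in the top 1143 calls of replicates 1, 2 and 4. CACTGT was chosen from these same IDR peaks, and the top calls of the replicates held 67.3% to 75.1% of the IDR summits. These shares are therefore not independent support for the arrangement. Outward hits lay at a median of 95 bp from the summit, and pairs of outward hits on opposite sides of a summit were a median of 177.5 bp apart.

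CACTGT and its reverse complement have the same GC content, so the AT-rich centres alone do not account for the arrangement. The outward share was 68.4% (interval 63.3 to 73.0) in pooled calls of ranks 1144 to 2500. Those calls were about as AT-rich as the IDR peaks, so their share does not test composition. The outward share fell gradually with rank, to 66.3% in ranks 2501 to 5000, 63.5% in ranks 5001 to 10000 and 55.8% in ranks 10001 to 20000. Ranks 20001 to 30000 gave 54.6% (51.6 to 57.5), still slightly above an even split. The arrangement was therefore not equally strong in every call, but it was not confined to the strong ones. An outward element on one side went with one on the other (62 peaks with both, odds ratio 9.84, interval 6.39 to 15.1), which argues against a single element with a displaced summit, and annotated transposable elements held 0 of the 215 summits with an outward element (0%, interval up to 1.76%), against 1.32% of the other calls. No biological explanation was tested, the factor that reads the sequence is not known from these data, and unannotated repeats and strand asymmetry of the sequence stay open.

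Cytosolic ribosomal protein genes exceeded the pool of 9 other housekeeping lists, in which 38 of 235 genes were bound (16.2%, interval 12.0 to 21.4), with an odds ratio of 3.46 (interval 1.88 to 6.31, Fisher's exact test, p = 3.56e-05), so housekeeping genes in general do not account for the excess. Against the lists one by one the odds ratios were 2.33 to 12 and 3 of 9 passed the adjusted threshold (proteasome, respiratory chain and splicing), whereas mitochondrial ribosomal proteins (2.40, adjusted exact p = 0.0887) and aminoacyl-tRNA synthetases (2.33, adjusted exact p = 0.186) were among those that did not, so a similar rate in single lists stays open. With each summit given to its nearest TSS alone the odds ratio against all other genes was 6.39 (interval 3.90 to 10.4), so peaks of neighbouring genes do not account for it. Transcription was not measured here, and ribosomal protein genes may be transcribed more strongly than the other lists, so signal that follows the level of transcription stays open. No biological explanation was tested.

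The replicate 2 list was richer in GC than the others, in its strongest calls and more so in its weaker ones. In ranks 1 to 250 the GC content was 38% in replicate 2, 34.2% in replicate 1 and 33.9% in replicate 4, and in ranks 2501 to 30000 it was 44.5%, 38.3% and 38.2%, a difference of 6.24 percentage points from the nearer one. Of the top 1143 summits of replicate 2, 627 lay in the top calls of replicate 1 and 554 in those of replicate 4, where 100 random draws gave at most 58 and 70, but 654 of the replicate 1 summits lay in those of replicate 4. A mislabelled sample is therefore not excluded, since regions called in many experiments or a shared control could give part of this overlap. A library with a GC-dependent background could also give the pattern, which was noticed before the test was chosen, and read depth and library preparation were not analysed here.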
